A study of Mus musculus with 6 samples.

How the data were processed

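Polyadenylated RNA was sequenced in 6 libraries of mouse fetal liver erythroblasts, 3 from untreated cells and 3 from cells treated with carbon dots (CDs, 1 ug/ml) for 30 h. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, fragmented, copied with random hexamers, amplified by PCR and read from one end over 50 bases on a DNA nanoball instrument. The protocol names no step that marks strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the mouse genome build GRCm38.p6, without the role or order of each tool.

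The authors deposited 2 tables of the same 17691 genes and 6 libraries. One holds expected counts per gene as the authors' processing estimated them, with 30.1% of the values not whole numbers. These deposited expected counts were rounded to whole numbers before any count test. The other deposited table holds FPKM, a unit worked out from the values: each count divided by its FPKM and by the library's total gives one length per gene for nearly all genes. The FPKM values served to check the counts gene by gene and were used in no test between groups. Genes were matched to the RefSeq annotation of GRCm38.p6 by Entrez number, which succeeded for 17570 genes (99.3%), and coordinates in the text are 1-based positions in that build. A spreadsheet had turned 24 symbols into dates, and these were restored from the annotation. Mitochondrially encoded genes were absent from the table used here (0 genes), so their share of counts was not analysed.

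Totals ran from 17695997 to 20066581 expected counts per library, a ratio of 1.13 between the largest and the smallest. A gene at 0 counts was given a floor of 3 counts per library, which covers counting error only, since PCR copies are not independent molecules. Within each group the libraries differed by far more than sampling noise, with a smallest chi-square per degree of freedom of 11.5, so none was a copy of another. The labels do not say whether replicates came from separate cultures, litters or days, and the p-values measure only the spread between these samples, which may be technical in part. Levels of Y-linked genes, given below, argue against 1 pool of cells behind all 3 replicate numbers.

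Genes were filtered with filterByExpr, which left 12283 genes holding 99.9% of the counts, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit and test, robust) in R 4.3.3, with treatment as the only term. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. CPM values use the TMM-scaled totals, means are given with the SD over 3 libraries, and fold changes carry the standard error of the edgeR fit. Unless a replicate block is named, that fit has none, and the spread between replicate numbers enters its standard errors. Before the data were examined, 39 gene lists were written, 31 of pathways and processes of erythroblasts or of cells exposed to nanoparticles and 8 of markers of other cell types that fetal liver can hold. Of these, the list of mitochondrially encoded genes had no member in the table, and the other 38 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Shares of counts, totals and numbers of detected genes were compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

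The named genes followed a rule fixed before the data were examined. Among genes with an adjusted p under 0.05, a mean of at least 1 CPM, no overlap between the groups and no predicted or clone name, it takes the 12 largest rises and the 12 largest falls. In a direction with no such gene it takes the 6 with the smallest unadjusted p as values that do not pass, which is what happened in both directions. These 6 in each direction were taken only from genes that met the other conditions, among them no overlap between the groups. Of the 6 on the lower side, 1 is not reported here. It adds up to 4 members with the smallest unadjusted p from each list described and 10 fixed genes (Hbb-bt, Hba-a1, Alas2, Gata1, Klf1, Epor, Tfrc, Slc4a1, Kit and Ptprc). Genes named outside the rule are said to be so.

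Both groups carry the replicate numbers 1 to 3 in the labels, and whether the numbers pair the libraries was checked before the calls of the fits were compared. Deviations from the group means, over all genes tested, correlated at 0.91 for number 1, 0.34 for number 2 and 0.94 for number 3, all above the limit of 0.1, and the numbers were therefore taken to pair the libraries. Of the 6 possible pairings, 2 pass that limit, and the other exchanges CDs 1 and CDs 2 (correlations of 0.14, 0.68 and 0.94). The summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was also alike by number, at 148 and 158 CPM in untreated 1 and CDs 1, 86.9 and 82.7 CPM in untreated 2 and CDs 2, and 36.2 and 40.2 CPM in untreated 3 and CDs 3. Such differences between numbers, alike in both groups, argue against replicates drawn from 1 pool of cells. A fit with the replicate number as a block was planned as an alternative and leaves 2 residual degrees of freedom, against 4 without the block.

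The edgeR steps were tested on simulated data with 12283 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. The changed genes were drawn from those averaging above 10 CPM, so recovery at lower levels was not tested. With counts drawn from the means of each numbered pair, the fit without the block recovered 1% of the 2-fold and 41% of the 4-fold changes and called 0 unchanged genes. On the same counts the fit with the replicate block recovered 97% and 99% and called 31 unchanged genes, a share of its calls above the threshold of 0.05. Recovery of changes that differ in size between pairs was not tested. In the real libraries Ccnd1 differed by 3.06, 2.64 and 1.38 (log2) in the numbered pairs. With the block Aldoc, Ccnd1, Csf3r and Egr1 had log2 fold changes of 2.30, 2.38, 2.52 and 2.72 and did not pass (edgeR adjusted p = 0.0916 for each). The recovery with the block therefore need not hold for the real data. With counts drawn from the means of all libraries and the wider spread, the fit without the block recovered 0% and 12%, and the fit with the block recovered 0% of either size.

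Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors within edgeR, library totals alone, scaling without globin genes, no filter, a filter at a mean of 1 CPM, glmTreat at a fold of 1.2, each library left out in turn, the replicate block, and for lists the estimated correlation, fry and camera on genes at 1 CPM or more. Chosen after seeing the data were DESeq2 with the block, limma-voom with and without it, both libraries numbered 3 left out, the mean log2 CPM (prior count of 2) of the macrophage markers as a covariate, and the estimated correlation and fry with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.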

Results

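RNA levels were measured in erythroblasts, the nucleated precursors of red blood cells, from the fetal liver of C57BL/6J mice. The cells lacked TER119, a surface antigen of later erythroid cells, and were grown with erythropoietin, the hormone that drives red cell production. Carbon dots are nanometre-sized carbon particles, made here from the medicinal plant Codonopsis pilosula. The 6 libraries form 2 groups of 3, untreated and treated with CDs (1 ug/ml, 30 h). The untreated libraries held 19920652, 19896958 and 20066581 expected counts, and the CDs libraries 17695997, 19992001 and 19899304. The design gives a single comparison, which asks which transcripts differ between treated and untreated erythroblasts.

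With CDs, genes of cholesterol synthesis, stem and progenitor cell genes and markers of several non-erythroid cell types rose as lists, while genes of the cytosolic ribosome, oxidative phosphorylation and DNA replication fell as lists. With an estimated correlation between genes 0 lists passed (smallest adjusted p = 0.140, for cholesterol synthesis). No single gene passed adjustment in the edgeR test without the replicate block, which recovered 1% of the 2-fold changes simulated from the pairs. The same test with the block called 5 genes, limma-voom with the block 7 and DESeq2 with it 1160. At an adjusted p under 0.10 these blocked fits called 1020, 1592 and 1608 genes. On all 6 libraries the largest list shifts upward were those of endothelial markers (median log2 fold change of 0.68), macrophage markers (0.67) and cholesterol synthesis (0.57), and the largest downward one was that of ribosomal protein genes (-0.30). Leaving out 1 library moved the median of all 21 called lists by over 1.5 times in at least 1 case. Without CDs 3 the 4 medians were -0.18, -0.76, 0.22 and -0.10, and without untreated 3 they were 1.71, 3.38, 0.69 and -0.49. These fits had no block, so the numbered partner of the library left out stayed in its group. All 21 lists kept their call and direction when both libraries numbered 3 were left out. Globin genes, the main transcripts of these cells, held 11.1% ± 0.269 (SD, n = 3) of the counts in untreated and 11.2% ± 0.925 (SD, n = 3) in CDs libraries, a difference within the spread between replicates (exact permutation p = 0.9, smallest possible 0.1). Of the 38 lists tested, camera at the preset correlation called 13 up and 8 down. Fry, which tests each list by itself, called 0 (smallest adjusted p = 0.151). With the replicate block the preset test called 24 lists, among them all 21 of the fit without it.

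**Figure D1:**
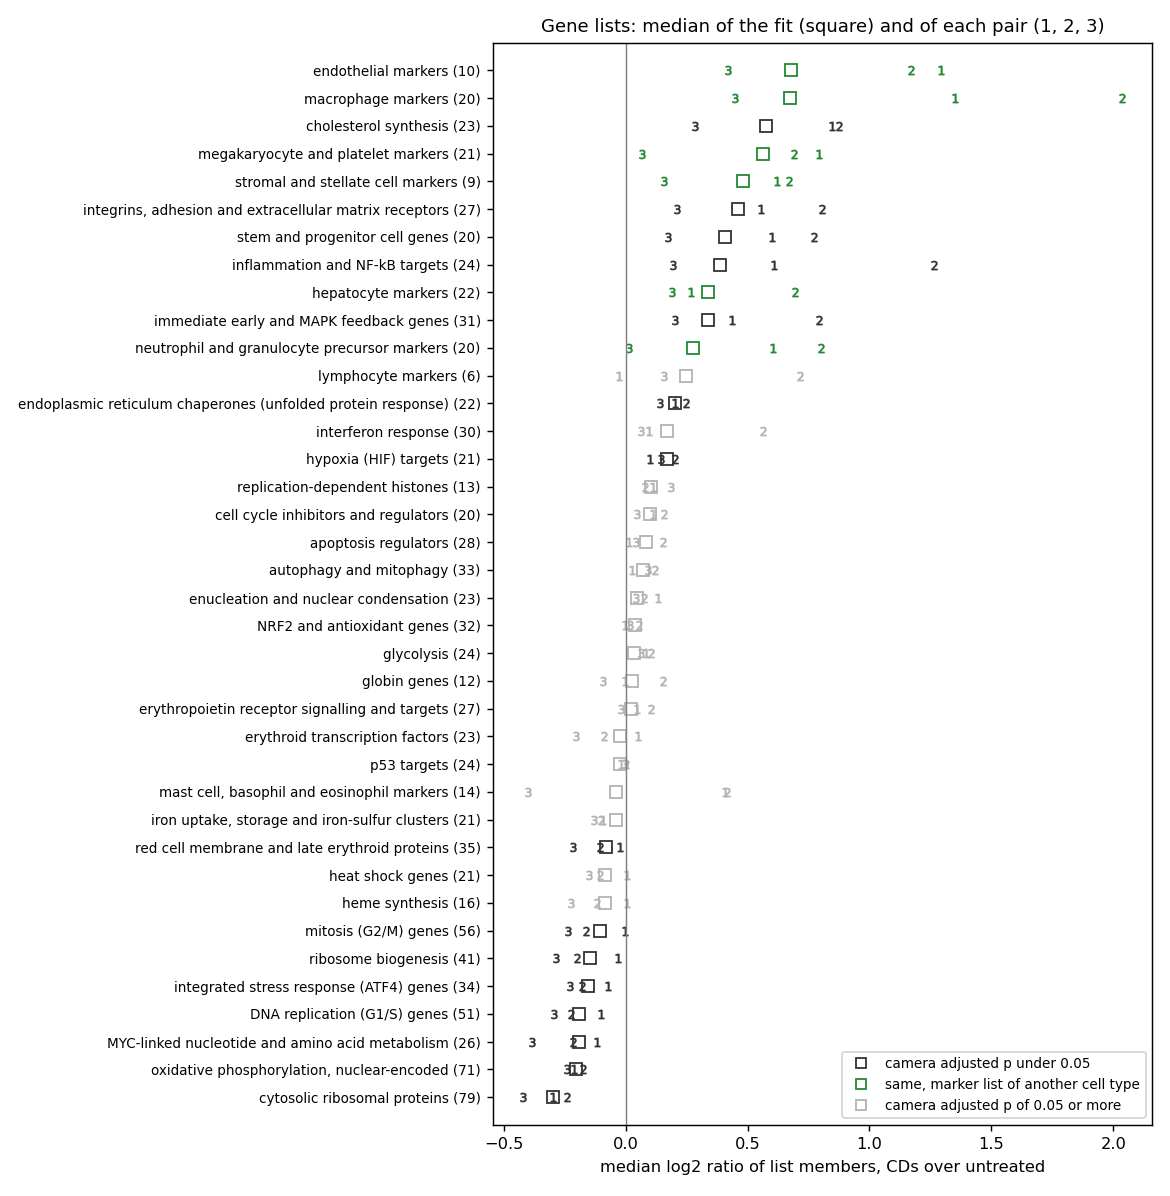
Median log2 ratio of CDs over untreated for each gene list, with the number of tested members in brackets; squares are medians of the edgeR fold changes and the digits 1, 2 and 3 the medians of the numbered pairs. Black and green mark lists with a camera adjusted p under 0.05 at the preset correlation, of which 13 lie above 0 and 8 below, and green marks the 6 that are markers of other cell types.

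The libraries differed along one main axis that treatment did not define. The first principal component of log2 CPM took 88.7% of the variance, with scores of -87.1, -46.2 and 74.6 in untreated 1 to 3 and -52.0, 14.9 and 95.7 in CDs 1 to 3. Treated and untreated means of this score differed by 39.1, less than the SD within either group (exact permutation p = 0.6). Within each numbered pair the treated library scored higher, by 35.1, 61.2 and 21.1. Macrophage markers followed the same axis, with 0.0254%, 0.0637% and 0.565% of the counts in untreated 1 to 3 and 0.0534%, 0.203% and 0.754% in CDs 1 to 3. Ribosomal protein genes ran against it, at 8.33%, 8.09% and 5.53% in untreated and 6.97%, 6.91% and 4.2% in CDs libraries, lower in the treated library of all 3 pairs (exact permutation p = 0.5 between groups). Total counts, detected genes and the share of the 10 most abundant genes gave exact permutation p-values of 0.5, 0.6 and 1. By pair, detected genes were higher in the treated library of all 3, by 133, 296 and 144. The other 2 measures were higher in 1 of 3 pairs.

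**Figure D2:**
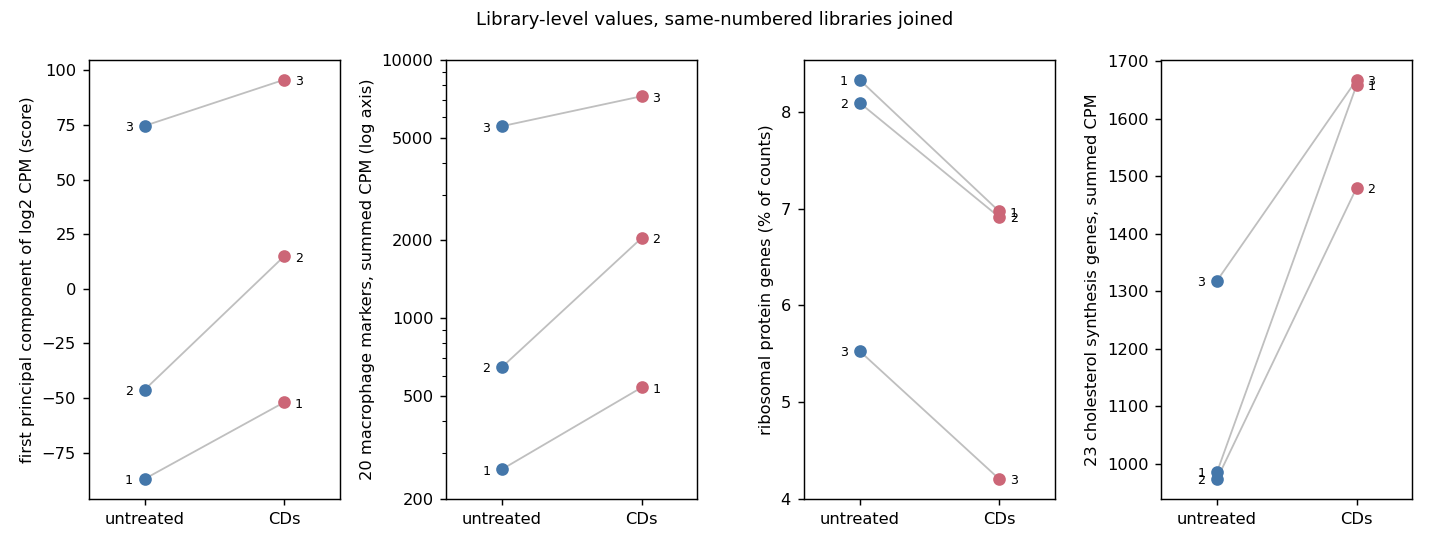
Each point is 1 library, with untreated libraries on the left and CDs libraries on the right of each panel, and lines join libraries of the same number; the panels show the score on the first principal component, the summed CPM of 20 macrophage markers on a log axis, the percent of counts in ribosomal protein genes and the summed CPM of 23 cholesterol synthesis genes. The score and the macrophage markers are higher and the ribosomal share is lower in the treated library of all 3 pairs. In these panels, but not in that of cholesterol synthesis, both libraries numbered 3 stand apart from the rest.

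On the higher side 6 single genes were taken by the smallest unadjusted p among genes without overlap between the groups. Aldoc, a glycolytic aldolase (Entrez 11676, chromosome 11, 78323073 to 78327781), measured 14.7 ± 3.53 CPM (SD, n = 3) untreated and 72.4 ± 13.6 CPM with CDs, a log2 fold change of 2.30 ± 0.24 (SE). Ccnd1, the G1 cyclin D1 (chromosome 7, 144929931 to 144939831), measured 16.8 ± 0.941 and 96.1 ± 48.8 CPM (log2 fold change of 2.51 ± 0.43). Csf3r, the receptor for granulocyte colony-stimulating factor (chromosome 4, 126023441 to 126044975), measured 12.4 ± 2.84 and 77.1 ± 39.9 CPM (2.63 ± 0.47). Egr1, an immediate early transcription factor (chromosome 18, 34861207 to 34864956), measured 15.6 ± 9.70 and 94.9 ± 15.9 CPM (2.60 ± 0.47). Hmox1, heme oxygenase 1, measured 4.9 ± 1.91 and 15.5 ± 0.619 CPM (1.66 ± 0.31), and Fads1, a fatty acid desaturase, 56.9 ± 0.353 and 84.1 ± 6.43 CPM (0.56 ± 0.11). In each of these 6 genes all 3 CDs libraries lay above all 3 untreated ones, which the choice required.

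On the lower side the genes were Slc26a1, Egfr, Ndufb7, Cox7b and Tnfrsf13c, again chosen among genes without overlap between the groups. Egfr, the epidermal growth factor receptor (chromosome 11, 16752203 to 16913907), measured 31.7 ± 7.95 CPM (SD, n = 3) untreated and 9.86 ± 1.82 CPM with CDs (-1.68 ± 0.26), and Slc26a1, an anion exchanger, 6.26 ± 0.561 and 2.17 ± 0.292 CPM (-1.52 ± 0.22). The respiratory chain genes Ndufb7, of complex I, and Cox7b, of cytochrome c oxidase, had log2 fold changes of -0.98 ± 0.22 and -0.81 ± 0.19. Tnfrsf13c, the BAFF receptor, measured 58.9 ± 2.74 and 41.2 ± 6.23 CPM (-0.52 ± 0.15). In Egfr, Ndufb7 and Cox7b the deposited counts and FPKM disagree between libraries by more than in 99% of the 8055 genes compared, with RMS log2 deviations of 0.106, 0.296 and 0.203 against a median of 0.00487 over those genes. In Egfr the disagreement is nearly gone (RMS of 0.0202) when counts are set against totals of the same-numbered library of the other group. Totals differ clearly only within pair 1, so this speaks to that pair alone. If both tables hold exchanged values in all 3 pairs, the direction of this gene would be opposite.

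**Figure D3:**
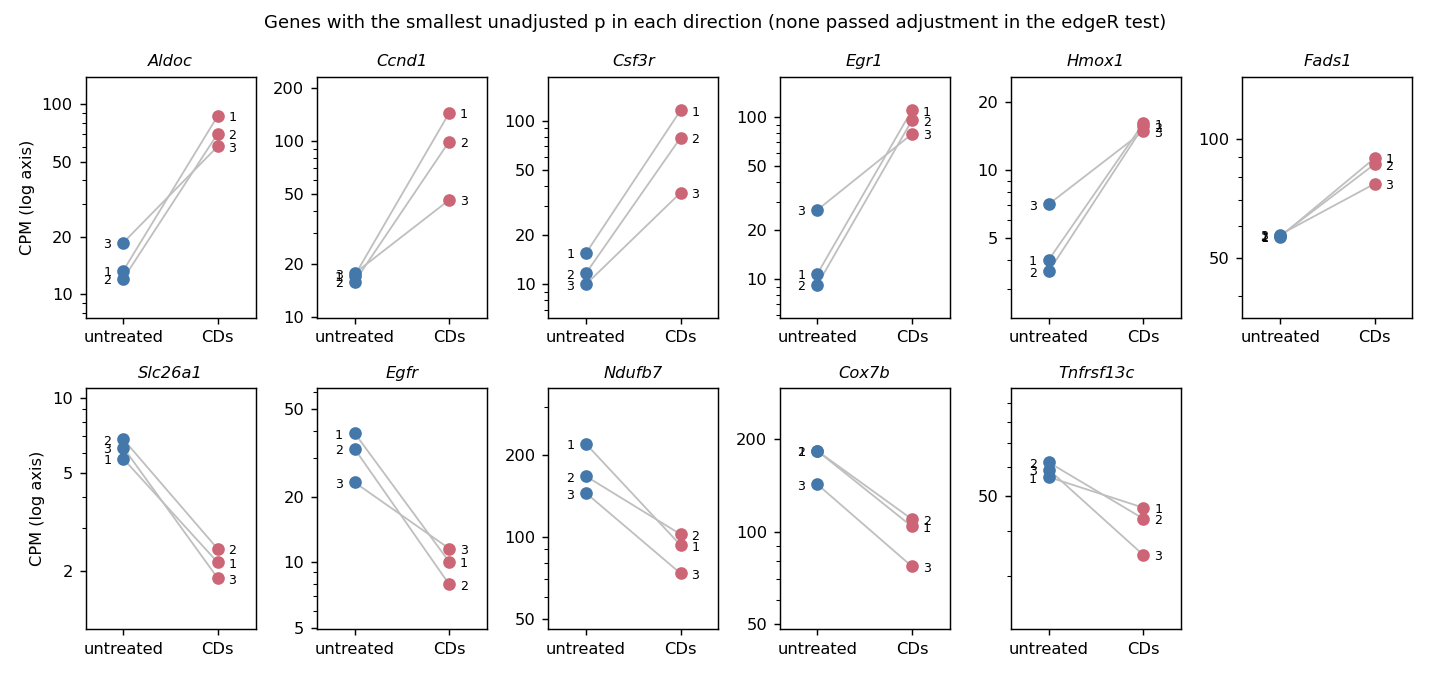
CPM per library on log axes for the 6 genes with the smallest unadjusted p on the higher side (top row) and for 5 of those on the lower side (bottom row), with untreated libraries on the left, CDs libraries on the right and lines joining libraries of the same number. The groups do not overlap in any of the 11 genes, which the choice required. None of them passed adjustment in the edgeR test without the replicate block, and Cox7b passed with it.

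None of the 12283 genes passed an adjusted p of 0.05 in the edgeR quasi-likelihood test without the block (smallest adjusted p = 0.994), while 127 had an unadjusted p under 0.05. In this test the spread between the numbered pairs counts as noise. The common coefficient of variation between libraries was estimated at 0.485 without the block and 0.112 with it. The 0 calls therefore do not show that no gene changed. Limma-voom also called 0 genes. DESeq2 called 11, 6 higher and 5 lower (7 and 4 with Egfr turned), among them Aldoc, Ccnd1, Csf3r, Egr1, Hmox1, Slc26a1 and Egfr. With the replicate block 3667 genes had an unadjusted p under 0.05 in edgeR, and 1020 had an adjusted p under 0.10. At the threshold of 0.05 edgeR with the block called 5 genes, named here after their values were seen. These were Aldh3b1, an aldehyde dehydrogenase (log2 fold change of 1.54 ± 0.08, edgeR adjusted p = 0.0221), Casp1, the inflammatory caspase (1.22 ± 0.09, adjusted p = 0.0452), Egln1, an oxygen-sensing prolyl hydroxylase (1.404 ± 0.11, adjusted p = 0.0490), Car1, an erythroid carbonic anhydrase (-0.93 ± 0.06, adjusted p = 0.0452), and Cox7b (-0.82 ± 0.06, adjusted p = 0.0452). Over all alternatives the adjusted p of these 5 genes ran from 2.80e-29 (Aldh3b1, DESeq2 with the block) to 1.00. Counts and FPKM of Casp1 disagree more than those of any other gene compared (RMS of 0.382). DESeq2 with the block called 1160 genes, 878 higher and 282 lower (879 and 281 with Egfr turned), and limma-voom with it 7. Groups did not overlap in 577 genes (4.70%), 291 higher and 286 lower. Chance gives 10% if all 6 libraries are exchangeable, which the pairing by number does not allow, and exchanging the libraries of 1 pair gave 193, 211 and 211 genes (1.57% to 1.72%). Further, 56.4% of genes moved the same way in all 3 pairs, against 25% for independent signs. Many genes follow the first principal component, on which the treated library was higher in all 3 pairs. The 25% is therefore no test of this share.

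Of the 10 genes fixed for naming, Hbb-bt and Hba-a1, adult globins, had log2 fold changes of -0.05 ± 0.16 and -0.05 ± 0.19, and Alas2, the first enzyme of erythroid heme synthesis, 0.04 ± 0.13. The values were -0.18 ± 0.34 for Gata1 and -0.21 ± 0.41 for Klf1, both erythroid transcription factors, -0.17 ± 0.36 for the erythropoietin receptor gene Epor, 0.02 ± 0.41 for the transferrin receptor gene Tfrc and -0.02 ± 0.20 for Slc4a1, the band 3 anion exchanger. Kit, the stem cell factor receptor, had 0.33 ± 0.26, and Ptprc, the leukocyte antigen CD45, 0.68 ± 1.29. None of these 10 passed in either edgeR fit. With the block Klf1 (-0.25 ± 0.08) and Epor (-0.20 ± 0.07) were lower in 3 of 3 pairs, and Ptprc (1.02 ± 0.23) was higher in 3 of 3 and passed in DESeq2 with the block (adjusted p = 0.000214, over all alternatives from 2.03e-06 to 1.00). Hba-a1 has a near-identical copy, Hba-a2, and reads could be divided between them. As lists, globin genes (median 0.03, adjusted p = 0.820) and erythropoietin receptor signalling (0.02, adjusted p = 0.822) did not pass with or without the block, and globin genes passed without CDs 3 (0.08, adjusted p = 0.0488). Heme synthesis (-0.09, adjusted p = 0.101) and erythroid transcription factors (-0.02, adjusted p = 0.207) did not pass without the block and passed with it, at adjusted p = 0.0461 and 0.0409, against 0.736 and 0.737 with an estimated correlation. Heme synthesis also passed without untreated 3 (-0.26), CDs 1 (-0.26) or CDs 2 (-0.16), and erythroid transcription factors without CDs 1 (-0.16). Iron uptake and storage (-0.04, adjusted p = 0.593) did not pass. The 35 red cell membrane and late erythroid genes fell as a list (median -0.08, adjusted p = 0.0195, and adjusted p = 0.763 with an estimated correlation), with 26 below 0 and Car1 at -0.90 ± 0.60. This list lost its call without untreated 2 (-0.03), without CDs 3 (0.04) and with the macrophage marker score as a covariate (0.02). It kept the call at -0.02 without untreated 1, -0.16 without untreated 3, -0.19 without CDs 1 and -0.15 without CDs 2.

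Ribosomal protein genes fell together. All 79 tested members had values below 0 in the fit and in each of the 3 pairs (camera adjusted p = 7.02e-22, and adjusted p = 0.763 with an estimated correlation). Examples were Rps14 (-0.38 ± 0.26), Rpl31 (-0.36 ± 0.26), Rpl23 (-0.34 ± 0.24) and Fau (-0.28 ± 0.18). No member passed without the block, over all genes or adjusted over the list alone, while with the block 78 of the 79 passed when adjusted over the list alone. The list kept its call with any 1 library left out, with medians of -0.20 without untreated 1, -0.49 without untreated 3 and -0.10 without CDs 3, and at -0.11 with the macrophage marker score as a covariate. Oxidative phosphorylation genes of the nucleus fell too, with 71 of 71 members below 0 and 70 below 0 in all 3 pairs (median -0.20, adjusted p = 7.13e-16, and adjusted p = 0.763 with an estimated correlation). Besides Ndufb7 and Cox7b, Ndufa3 had -0.28 ± 0.15 and Ndufa7 -0.26 ± 0.14, and 49 members passed with the block when adjusted over the list alone. This list too kept its call, with medians of -0.12 without untreated 1, -0.35 without untreated 3, -0.31 without CDs 2 and -0.06 without CDs 3, and at -0.06 with the covariate. In CDs 1 to 3 the macrophage markers were higher than in their numbered partners by medians of 1.35, 2.04 and 0.45 (log2), beside these falls of -0.30, -0.24 and -0.42 in ribosomal protein genes.

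Proliferation and biosynthesis lists fell too. DNA replication genes had 51 of 51 members below 0 (median -0.19, adjusted p = 8.50e-08), among them Rfc2 (-0.30 ± 0.23), Prim1 (-0.29 ± 0.28) and Rpa2 (-0.30 ± 0.29). Mitosis genes had 51 of 56 below 0 (median -0.11, adjusted p = 0.000453), with Cks2 at -0.33 ± 0.29 and Cdca3 at -0.25 ± 0.27. Ribosome biogenesis (median -0.15, adjusted p = 0.00113, with Nop56 at -0.43 ± 0.49), MYC-linked nucleotide and amino acid metabolism (-0.19, adjusted p = 0.00497, with Shmt2 at -0.31 ± 0.34) and ATF4-dependent stress response genes (-0.15, adjusted p = 0.000699, with Cth at -0.77 ± 0.37) fell as well. Each of these 5 lists had an adjusted p = 0.763 with an estimated correlation. By summed CPM all 5 were also lower in untreated 3 than in untreated 1. The sums in untreated 1 to 3 were 13321, 13236 and 8685 for DNA replication and 24752, 25093 and 17539 for mitosis. They were 6167, 5316 and 3027 for ribosome biogenesis, 10905, 10015 and 6157 for MYC-linked and 8400, 8078 and 6288 for ATF4-dependent genes. Without CDs 3 each of the 5 lost its call, and the medians of DNA replication (0.0015), mitosis (0.09), ribosome biogenesis (0.11) and MYC-linked genes (0.06) turned positive, with mitosis and ribosome biogenesis called up. Mitosis and MYC-linked genes also lost the call without untreated 1 (medians of -0.02 and -0.02) or untreated 2 (-0.03 and -0.12), and ribosome biogenesis without untreated 1 (0.04). Calls were kept for DNA replication at -0.09 without untreated 1, -0.10 without untreated 2, -0.37 without untreated 3, -0.38 without CDs 1 and -0.30 without CDs 2, for mitosis at -0.27 without untreated 3, -0.28 without CDs 1 and -0.20 without CDs 2, and for ribosome biogenesis at -0.09 without untreated 2, -0.38 without untreated 3 and -0.45 without CDs 1. They were also kept for MYC-linked genes at -0.43 without untreated 3 and -0.46 without CDs 1, and for ATF4-dependent genes at -0.09 without untreated 1 and -0.23 without CDs 1, with the latter at -0.02 without CDs 3. All 5 kept the call and the direction when both libraries numbered 3 were left out. With the macrophage marker score as a covariate mitosis (0.08, adjusted p = 0.0387) and ribosome biogenesis (0.13, adjusted p = 0.00144) were called up, and DNA replication (0.0030), MYC-linked (0.07) and ATF4-dependent genes (-0.04) lost the call. With the block, 25 DNA replication genes and 11 MYC-linked genes passed when adjusted over the list alone.

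Cholesterol synthesis genes rose as a list, with 20 of 23 members above 0 and 18 above 0 in all 3 pairs (median 0.57, adjusted p = 2.84e-07, and adjusted p = 0.140 with an estimated correlation). Fdft1, squalene synthase, measured 69.5 ± 5.93 CPM untreated and 133 ± 47.2 CPM with CDs (0.94 ± 0.30). Hsd17b7 had 1.24 ± 0.45, Stard4, a sterol carrier, 0.91 ± 0.44, and Ebp, a sterol isomerase, 0.26 ± 0.11. With the block 10 members passed when adjusted over the list alone. The list kept its call with any 1 library left out, with medians of 0.22 without untreated 1, 0.34 without untreated 2 and 0.22 without CDs 3, and at 0.24 with the macrophage marker score as a covariate. Hypoxia-inducible factor targets rose (16 of 21 above 0, median 0.17, adjusted p = 0.00775, and adjusted p = 0.316 with an estimated correlation), led by Egln1 (1.44 ± 0.35), the mitophagy receptor gene Bnip3 (1.71 ± 0.43) and Pdk1 (1.19 ± 0.41). This list lost its call without untreated 3 (median 0.29, adjusted p = 0.1504) and without CDs 2 (0.16, adjusted p = 0.158), and kept it at 0.41 without CDs 1 and 0.10 without CDs 3. Over all alternatives the median of the hypoxia list ran from 0.0474 to 0.41. Glycolysis as a list did not pass (median 0.04, adjusted p = 0.0530). It passed without untreated 1 (adjusted p = 0.00269), untreated 2 (adjusted p = 0.0438) or CDs 3 (adjusted p = 8.64e-05), with the covariate (adjusted p = 0.000449), with DESeq2 size factors (adjusted p = 0.0497) and, with the block, without both libraries numbered 3 (adjusted p = 0.0436), and Aldoc was its 1 member to pass when adjusted over the list alone.

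Signalling and surface receptor lists rose. Immediate early genes had 27 of 31 members above 0 (median 0.34, adjusted p = 0.000378), with Egr1, Ier2 (0.35 ± 0.21) and Fos (0.61 ± 0.43) in front. Integrins and matrix receptors had 24 of 27 above 0 (median 0.46, adjusted p = 0.00775), with Itgb3 at 0.64 ± 0.33 and Spp1 at 1.36 ± 1.65. Inflammation and NF-kB targets had 21 of 24 above 0 (median 0.39, adjusted p = 0.0241), with Tnf at 0.338 ± 0.0849 CPM untreated and 1.02 ± 0.174 CPM with CDs (1.57 ± 0.32). The other members of this list that the naming rule takes were Nfkb1 (-1.47), Tnfaip2 (-0.22) and Nfkb2 (0.19). Nfkb1 stayed below 0 over all alternatives, from -2.57 to -0.42. Stem and progenitor cell genes had 18 of 20 above 0 (median 0.41, adjusted p = 3.40e-05), with Sox4 at 0.70 ± 0.23 and Myb at 0.32 ± 0.19. Endoplasmic reticulum chaperones had 17 of 22 above 0 (median 0.20, adjusted p = 0.0335), with Hyou1 at 0.18 ± 0.17. With an estimated correlation each of these 5 lists had an adjusted p = 0.763. Stem and progenitor genes kept the call with any 1 library left out, at 0.14 without untreated 1, 0.82 without untreated 3 and 0.14 without CDs 3. The other 4 lost it without CDs 3, with medians of -0.13 for immediate early genes, -0.19 for integrins, -0.65 for NF-kB targets and 0.01 for chaperones. The latter 3 also lost it without untreated 1 (0.04, -0.10 and 0.09) or untreated 2 (0.10, 0.05 and 0.11), and chaperones without CDs 2 (0.27, adjusted p = 0.0735). Chaperones also lost it without a filter (0.19), and NF-kB targets with a filter at a mean of 1 CPM (0.39) or with camera on such genes (0.39). Immediate early genes kept it at 0.10 without untreated 1, 0.06 without untreated 2, 1.04 without untreated 3 and 0.58 without CDs 1, integrins at 1.3996 without untreated 3 and 0.76 without CDs 1, NF-kB targets at 2.23 without untreated 3, 0.85 without CDs 1 and 0.58 without CDs 2, and chaperones at 0.45 without untreated 3 and 0.33 without CDs 1. With the macrophage marker score as a covariate NF-kB targets were called down (-0.20, adjusted p = 9.02e-06) and stem (0.11), immediate early (0.09), integrin (-0.02) and chaperone genes (0.03) lost the call. The interferon response list (median 0.17, adjusted p = 0.641) was called up with the block (adjusted p = 0.00258, and adjusted p = 0.736 with an estimated correlation), without untreated 3 (1.48), without CDs 1 (0.63) and, with the block, without both libraries numbered 3 (0.32). It was called down without untreated 1 (-0.23), without CDs 3 (-0.81) and with the covariate (-0.46).

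Markers of other cell types were tested because the TER119-negative fraction can hold such cells. Of the 8 lists, 6 rose and 0 fell. Macrophage markers had 19 of 20 members above 0 (median 0.67, adjusted p = 0.000372), with Csf1r at 224 ± 301 CPM untreated and 386 ± 360 CPM with CDs, Mrc1 at 1.48 ± 1.17 and Cx3cr1 at 1.24 ± 1.24. Endothelial markers had 9 of 10 above 0 (median 0.68, adjusted p = 0.000372), led by Flt1, a VEGF receptor, at 145 ± 12.3 and 372 ± 112 CPM (1.36 ± 0.26), and by Tie1 (1.21 ± 0.26), the 2 members that passed when adjusted over the list alone. Flt1 did not follow its list across libraries, at 3052, 2821 and 2725 counts in untreated 1 to 3 and 8268, 7769 and 5233 in CDs 1 to 3. The list median was 2.95, 4.17 and 15.2 CPM untreated and 3.72, 8.53 and 14.5 CPM with CDs. Megakaryocyte markers had 19 of 21 above 0 (median 0.56, adjusted p = 1.91e-08), with Pf4 at 1.04 ± 0.26 and Rab27b at 1.06 ± 0.33. Stromal (median 0.48, adjusted p = 0.000690, with Sparc at 0.60 ± 0.26), hepatocyte (0.34, adjusted p = 0.000253, with Apob at 0.63 ± 0.23) and granulocyte markers (0.28, adjusted p = 0.00662, with Csf3r and Prtn3 at 0.63 ± 0.65) rose too. Csf3r did not follow its list either, at 301, 229 and 205 counts in untreated 1 to 3 and 2028, 1569 and 754 in CDs 1 to 3. The granulocyte share rose from 0.0376% in untreated 1 to 0.394% in untreated 3, and from 0.0657% in CDs 1 to 0.408% in CDs 3. Mast cell (-0.04, adjusted p = 0.820) and lymphocyte markers (0.25, adjusted p = 0.433) did not pass. Mast cell markers were called down without untreated 1 (-0.48) and with the macrophage marker score as a covariate (-0.39) and up without untreated 3 (1.06), and lymphocyte markers up without CDs 1 (0.80). With an estimated correlation the adjusted p was 0.233 for the endothelial and stromal lists, 0.341 for the megakaryocyte list and 0.763 for the macrophage, hepatocyte and granulocyte lists. Without CDs 3 the number of lists called was 3 rather than 6, and the macrophage median was then -0.76. Macrophage and granulocyte markers also lost the call without untreated 1 (medians of 0.13 and -0.18), hepatocyte markers without untreated 2 (0.12) and without CDs 3 (-0.07), and granulocyte markers without CDs 2 (0.29, adjusted p = 0.0767, against 0.28 on all libraries) and without CDs 3 (-0.30). Endothelial markers kept the call at 0.42 without untreated 1, 0.30 without untreated 2 and 1.71 without untreated 3, and also without CDs 3, where the median was -0.18 and the test still pointed up (adjusted p = 0.000590). Calls were kept for macrophage markers at 0.19 without untreated 2, 3.38 without untreated 3 and 1.197 without CDs 1, for granulocyte markers at 0.09 without untreated 2, 1.32 without untreated 3 and 0.71 without CDs 1, and for hepatocyte markers at 0.21 without untreated 1 and 0.74 without untreated 3. Megakaryocyte markers kept it at 0.33 without untreated 1 and 0.37 without untreated 2, and stromal markers at 0.28 without untreated 2 and 0.27 without CDs 3. With both libraries numbered 3 left out the number stayed at 6, and with the block in addition it was 7 of 7 tested, with mast cell markers called up (0.41, adjusted p = 0.0208). With the macrophage marker score as a covariate hepatocyte (0.05) and granulocyte markers (-0.26) lost the call, and endothelial (0.35), megakaryocyte (0.38) and stromal markers (0.50) kept it. The score is made of the macrophage markers, so that fit does not test their own list.

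The remaining lists did not pass. Cell cycle inhibitors and regulators, which hold Ccnd1, had a median of 0.10 (adjusted p = 0.0796), autophagy and mitophagy genes 0.07 (adjusted p = 0.130), enucleation genes 0.04 (adjusted p = 0.449), replication-dependent histones 0.10 (adjusted p = 0.601) and apoptosis regulators 0.08 (adjusted p = 0.621). P53 targets (-0.02), NRF2 and antioxidant genes (0.04) and heat shock genes (-0.08) each had an adjusted p = 0.769. Cell cycle inhibitors passed without untreated 2 (adjusted p = 0.0425), without CDs 3 (adjusted p = 0.00939) and, with the block, without both libraries numbered 3 (adjusted p = 0.0350), and heat shock genes without untreated 1 (adjusted p = 0.0121) and CDs 3 (adjusted p = 3.72e-05) and with the macrophage marker score as a covariate (adjusted p = 1.91e-06). The mean of the p53, heat shock and iron lists was above 0 and their median below it, and the camera direction was up for the heat shock and mast cell lists, whose medians lay below 0. Hmox1 belongs to the iron, NRF2 and macrophage lists alike. Among heat shock genes Hspa1b measured 2.31 ± 0.638 and 8.43 ± 4.17 CPM (1.86 ± 0.47), a gene with a near-identical copy, Hspa1a, so that reads could be divided between them.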

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

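Over all the alternatives run, 2955 values of named genes kept their direction and side of the threshold, 186 newly passed and 67 changed direction without a call. Of the composition values, 26 kept their direction and 5 changed it, none with a call. Among list results 545 kept their direction and side of the threshold, 115 lost a call, 26 gained one and 70 changed direction, 23 of these with a call. The fits with DESeq2 and the block, limma-voom, both libraries numbered 3 left out, the macrophage covariate and the blocked estimated correlation and fry were chosen after seeing the data. The other scalings, both other filters, glmTreat, limma-voom and both libraries numbered 3 left out (each without the block) and each library left out in turn left the number of changed genes at 0, and the other scalings and filters gave 20 to 22 called lists. The fit with the replicate block called 5 genes, 3 higher and 2 lower, added 3 lists to the 21 and changed no other call. DESeq2 called 11 genes, 6 higher and 5 lower, or 7 and 4 with Egfr turned, whose values may be exchanged. DESeq2 with the replicate block called 1160, 878 higher and 282 lower (879 and 281 with Egfr turned). Limma-voom with the replicate block called 7, 4 higher and 3 lower. With both libraries numbered 3 left out, edgeR with the replicate block called 1835 genes, 1476 higher and 359 lower, from 2 pairs. With the macrophage marker score as a covariate and no block edgeR called 70, 40 higher and 30 lower (41 and 29 with Egfr turned). Camera with an estimated correlation called 0 lists and 0 of the lists of other cell types, and so did the same test with the replicate block (0 and 0), fry (0 and 0) and fry with the replicate block (0 and 0). The blocked tests had 2 residual degrees of freedom. Even ribosomal protein genes, with 79 members lower in all 3 pairs, had an adjusted p of 0.696 in blocked camera and 0.219 in blocked fry. Without the block the spread between pairs enters the estimated correlation, 0.979 for this list. These 0 calls are therefore weak evidence against a shift. With 1 library left out the number of called lists of other cell types ran from 3 (without CDs 3) to 7. Where the direction of the test changed, the value (the median, for lists) was as follows, and a median can keep its sign. Without a filter 0.0147 for globin genes, 0.00560 for erythropoietin receptor signalling and 0.13 for histones, with fry -0.0234 for p53 targets, with blocked fry -0.0124 for p53 targets and -0.10 for heat shock genes, without both libraries numbered 3 0.0167 for NRF2 genes, -0.0513 for heat shock genes, 0.0353 for histones, 0.00263 for Slc4a1, -0.00988 for Casp9 and 0.19 for Mcpt8. With the replicate block -0.10 for heat shock genes and -0.0189 for Tfrc, with a mean of 1 CPM or more -0.0783 for heat shock genes, with camera on genes at 1 CPM or more -0.0869 for heat shock genes, with the blocked estimated correlation -0.10 for heat shock genes. Without both libraries numbered 3 and with the block -0.0600 for heat shock genes, 0.0305 for histones, 0.00114 for Slc4a1, -0.0111 for Casp9 and 0.18 for Mcpt8, with DESeq2 size factors -0.000912 for Tfrc, with DESeq2 -0.0122 for Tfrc, with DESeq2 and the block -0.0495 for Tfrc. With limma-voom -0.0153 for Tfrc, with limma-voom and the block -0.0206 for Tfrc. With the macrophage covariate it was 0.0484 for heme synthesis, -0.00219 for iron handling, 0.0302 for erythroid transcription factors, -0.0111 for erythropoietin receptor signalling, 0.0776 for mitosis, -0.0422 for apoptosis regulators, 0.0193 for enucleation, 0.0285 for endoplasmic reticulum chaperones, -0.46 for interferon response and -0.20 for NF-kB targets. The covariate also gave -0.0230 for integrins, 0.13 for ribosome biogenesis, 0.0697 for MYC-linked metabolism, -0.26 for granulocyte markers, -0.39 for mast cell markers, -0.13 for lymphocyte markers, 0.0218 for Hba-a1, 0.0302 for Gata1, 0.0764 for Klf1 and 0.0926 for Epor. It further gave 0.0657 for Slc4a1, -0.0283 for Ptprc, -0.18 for Ifi44, -0.37 for Ddx58, 0.0137 for Paics, -0.0325 for Elane, -0.0731 for Epx, -0.22 for Prg2, -0.0249 for Cd79b and -0.14 for Nkg7. Last, it gave -0.13 for Il7r. With 1 library left out the values ran from -0.0776 to 0.0824 for globin genes, from -0.26 to 0.0744 for heme synthesis, from -0.18 to 0.00823 for iron handling, from -0.19 to 0.0359 for red cell membrane genes, from -0.16 to 0.0398 for erythroid transcription factors, from -0.000592 to 0.17 for erythropoietin receptor signalling, from -0.38 to 0.00149 for DNA replication, from -0.28 to 0.0894 for mitosis and from -0.0906 to 0.19 for apoptosis regulators. They ran from -0.0383 to 0.0454 for NRF2 genes, from 0.0126 to 0.45 for endoplasmic reticulum chaperones, from -0.28 to 0.16 for heat shock genes, from -0.81 to 1.48 for interferon response, from -0.65 to 2.23 for NF-kB targets, from -0.45 to 0.11 for ribosome biogenesis, from -0.46 to 0.0561 for MYC-linked metabolism, from 0.0727 to 0.25 for histones and from -0.76 to 3.38 for macrophage markers. Ranges went from -0.30 to 1.32 for granulocyte markers, from -0.48 to 1.06 for mast cell markers, from -0.32 to 0.98 for lymphocyte markers, from -0.12 to 0.00530 for Hbb-bt, from -0.15 to 0.0454 for Hba-a1, from -0.0213 to 0.0896 for Alas2, from -0.42 to 0.0746 for Gata1, from -0.47 to 0.0871 for Klf1 and from -0.41 to 0.0816 for Epor. Values lay from -0.30 to 0.29 for Tfrc, from -0.13 to 0.0978 for Slc4a1, from -0.52 to 2.63 for Ptprc, from -0.0729 to 0.65 for Hbb-y, from -0.39 to 1.11 for Hbb-bh1, from -0.00476 to 0.34 for Trp53inp1, from -0.31 to 0.0301 for Eif2ak2, from -1.08 to 3.29 for Ifi44 and from -0.68 to 1.72 for Ddx58. Further ranges went from -0.46 to 3.93 for Spp1, from -0.46 to 0.0115 for Paics, from -0.27 to 2.91 for Csf1r, from -1.76 to 0.58 for Prss34, from -0.31 to 1.395 for Epx, from -0.32 to 1.21 for Prg2, from -1.42 to 1.197 for Mcpt8, from -0.42 to 3.20 for Cdh5 and from -0.36 to 3.21 for Cd4. The range was from -0.0542 to 0.17 for Cd79b, from -0.0562 to 0.75 for Nkg7, from -0.48 to 2.42 for Il7r, from -0.47 to 0.43 for the globin share and from -0.51 to 0.49 for the share of the 10 most abundant genes. The cause was not tested, and each fit that left out 1 library kept its numbered partner, without a block. When CDs 3 was left out, untreated 3 stayed, with 0.565% of its counts in macrophage markers. When untreated 3 was left out, CDs 3 stayed (0.754%). Libraries numbered 1 and 2 held 0.0254% to 0.203%. Depth limits the genes near 1 CPM, such as Tie1 with 9, 12 and 12 counts untreated and 24, 28 and 23 with CDs.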

Other observations

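The tests on cell mixture, on depth, on the agreement of the deposited tables and on splits of the libraries were chosen after the results were seen, while those on short transcripts and scaling were written before. A test on depth written before, thinning to the smallest total, had little to remove and was set aside.

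Genes of lipid handling and signalling, outside the lists and chosen after their values were seen, had the following values without passing in edgeR. Abcg1, a cholesterol exporter, measured 106, 105 and 263 CPM in untreated 1 to 3 and 10.2, 14.6 and 91.6 CPM in CDs 1 to 3 (log2 fold change of -2.02 ± 0.98 SE). Pank3, a pantothenate kinase of coenzyme A synthesis, had 1.08 ± 0.20, and Timp3, an inhibitor of metalloproteinases, 1.45 ± 0.29. The kinase genes Pik3cd and Jak3 had 1.21 ± 0.25 and 1.14 ± 0.50, both higher in 3 of 3 pairs.

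Some multi-copy genes were at 0 in one group, and reads could not be placed among their copies with certainty. Gm4724 had 125, 118 and 65 counts untreated and 0 in all 3 CDs libraries, at least 33.5-fold lower against a floor of 3 counts per library (DESeq2 adjusted p = 1.28e-08). Duxbl3 had 11, 11 and 13 counts untreated and 0 with CDs, at least 3.78-fold lower (DESeq2 adjusted p = 0.0217), and its relative Duxbl2 had 0 untreated and 3, 11 and 25 counts with CDs.

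Between untreated 2 and untreated 1, where macrophage markers were higher by a median of 1.19 (log2), the cholesterol synthesis median was 0.05, against 0.85, 0.87 and 0.28 in the 3 pairs of CDs over untreated. For stem and progenitor genes it was 0.59, against 0.60, 0.77 and 0.17, so that these rose as much between the untreated libraries as in pair 1, and between untreated 3 and untreated 1 they rose by 1.37. Hypoxia targets had 0.07, against 0.10, 0.20 and 0.15, and oxidative phosphorylation genes -0.06, against -0.21, -0.17 and -0.24. Between untreated 3 and untreated 1 oxidative phosphorylation genes had -0.50, a larger fall than in any pair, hypoxia targets -0.13 and cholesterol synthesis 0.14.

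Markers of 6 other cell types were higher with CDs, although the starting cells were depleted of TER119-positive cells only. Whether all other cells took a larger share alike stays open. The macrophage median exceeded the mast cell median by 1.12 in the mean of the pairs, with a spread of 0.165 over marker genes. Both lists were picked after the results were seen. The macrophage list had the highest of the 8 medians in each pair, and the mast cell list the lowest in pairs 2 and 3. A gap between lists so picked cannot decide this. Without both libraries numbered 3 and with the block the mast cell list rose too (0.41), beside a macrophage median of 1.77. Depth is argued against. Totals differed by 0.00687 and -0.0121 (log2) in pairs 2 and 3, where the macrophage median was 2.04 and 0.45, with spreads of 0.151 and 0.0881. More macrophages in each treated library may be part of it, since across genes, which are not independent replicates, pair ratios followed the ratio of the other untreated libraries with r = 0.568, 0.783 and 0.217, the smallest value leaving it open. Csf1r, an abundant marker, measured 28.0, 74.3 and 571 CPM in untreated 1 to 3 and 82.5, 291 and 784 CPM in CDs 1 to 3, 7 of the 20 macrophage markers reached 10 CPM in untreated 1, 4 belong to another list, and an effect of CDs on such cells stays untested.

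Ribosomal protein genes were lower with CDs in all 3 pairs. Scaling is argued against, since the median stayed between -0.28 and -0.32 under 3 other scalings. More macrophages as the source stays open. Macrophage markers held 0.0254% of the counts in untreated 1, 0.0637% in untreated 2 and 0.0534% in CDs 1. Their share thus rose less in pair 1 than from untreated 1 to untreated 2, where the ribosomal fall was smaller. Each of these values rests on 1 library. The ribosomal median was -0.0530 between untreated 2 and untreated 1 and -0.30 in pair 1, while macrophage markers differed by 1.19 and 1.35, but between untreated 3 and untreated 1 it was -0.63, beside a macrophage difference of 4.68. With the macrophage marker score as a covariate it was -0.11, still called. A loss of short transcripts may account for a part, since 143 genes matched on length and level had a median of -0.11, a share of 0.351 of the ribosomal one. The matched genes remained longer (median implied length of 1330 against 664 bases), which keeps it open, and an effect of CDs on the cells stays open too.

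Of the 121 genes that the naming rule takes and that were compared, 4 lie among the 80 genes of 8055 whose counts and FPKM disagree most (one-sided Fisher exact p = 0.0320). All 4 belong to the 12 with the smallest unadjusted p or a call with the block (one-sided Fisher exact p = 4.20e-06 for these alone, a set chosen after the results were seen). In Egfr, Gstm5 and Gstt3 the deviations go with untreated and treated values exchanged in both tables (RMS from the exchanged totals of at most 0.0202). Of the genes compared, 4 lay within 0.03 of the exchanged totals, these 3 among them, and 0 lay as near to the mirror image. Totals of CDs over untreated differed by -0.171 (log2) in pair 1, but by 0.00687 and -0.0121 in pairs 2 and 3. The test therefore cannot show an exchange in pairs 2 and 3. A different mix of transcripts between libraries was not tested for these 3 genes. For Casp1, Ndufb7 and Cox7b a different mix stays open, since 9 of 9 pair directions were the same in FPKM and counts, which either source would give. How an exchange arose cannot be read from these tables, and no biological explanation was tested.

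The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes in edgeR and the highest other 3507, so all 10 gave at least as many. That other split set untreated 1, untreated 2 and CDs 1 against the rest, along the first principal component, and points to a structure of the samples. For lists the real split gave 21 and the highest other 25, with 5 splits at 21 or more, and for lists of other cell types 6 and 6, with 2 splits. DESeq2 gave 11 genes for the real split and 5666 for the highest other, with 2 splits at 11 or more. With the replicate block there are 4 splits, again too few, and the other 3 each exchange the libraries of 1 pair. The real split gave 5 genes in edgeR, 1160 in DESeq2 and 24 lists, the highest others 0, 0 and 18, and in each case 1 split, the real one, reached its value.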
